A study of Stylonychia lemnae with 6 samples.

How the data were processed

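The series holds 6 RNA-seq libraries of Stylonychia lemnae, a hypotrich ciliate, made from control cultures and from cultures given 10 µg/ml human EGF for 96 h, 108 h or 120 h. Per the labels, cells were grown in distilled water on the green alga Chlorogonium elongatum, the alga was removed with a filter before RNA was extracted, and equal amounts of RNA from 3 cultures were pooled into each library. Sequencing was paired-end on the HiSeq2000 platform. The submitters' processing notes name TopHat2, Cufflinks and TopHat, with neither versions nor roles. The authors deposited 1 table of FPKM values (fragments scaled to transcript length and library depth, per the file headers) with a contig, start, end and product description for each of 21061 genes. The genome build and annotation release are not given in the sources used here, and no reference genome was used. Groups were taken from the labels.

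Values were used as log2(FPKM + 1), with a pseudocount of 1. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 16577 in all, of which 7232 have a product name and 9345 are hypothetical or unnamed. FPKM holds no counts, so the depth was read from the values: at loci where FPKM times bp stayed under 400, the ratio of the same locus between libraries clusters at the ratio of the value of 1 fragment. This put the libraries at 1, 0.931, 1.11, 0.974, 1.44 and 1.55 times the depth of the control at 96 h, in the order control and EGF at 96 h, at 108 h and at 120 h. Counting intervals cannot be given for single genes without counts. The shares of summed FPKM in the 10 highest genes were 8.73% to 10.8%, and 1221 to 1545 genes per library are listed at 0.

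Similarity was described by Pearson's r and a principal component analysis. The EGF effect at each time was a log2 ratio of 1 library to 1 library, counted at 2-fold, with no test. The EGF effect over the time points was tested with limma (lmFit and eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg over tested genes, threshold 0.05), with the 3 times as a block, which leaves 2 residual degrees of freedom and 7.03 prior ones. The spread in this test is that of the EGF ratio between times, so a change at a single time counts as spread. With a pair left out this hardly held, as described with the calls without the 120 h pair. Time was tested the same way with treatment as a block (108 h against 96 h, 120 h against 96 h, 120 h against 108 h, and the F test), so that its spread is the difference between the treatments in their change over time. A product of treatment with linear time in hours tested whether the effect changed in a straight line over time. All p-values for single genes and lists come from limma.

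Before the data were examined, 26 gene lists were fixed as patterns in product names, together with the tests, the named-genes rule and most of the alternatives. The lists cover ribosomal proteins, ribosome biogenesis, translation factors and tRNA synthetases, DNA replication, cell cycle and mitosis, histones, meiosis and DNA repair, small RNA and genome rearrangement, cilia and axoneme, kinesins and myosins, protein kinases, EGF-like and growth factor names, MAPK, PI3K, TOR and Ras signalling, and cyclic nucleotide and calcium signalling. They further cover heat shock proteins and chaperones, proteasome and ubiquitin, lysosomal hydrolases and proteases, vesicle traffic and V-ATPase, autophagy, glycolysis and gluconeogenesis, citric acid cycle and oxidative phosphorylation, lipid metabolism, redox and detoxification, transporters and ion channels, food alga and photosynthesis, and bacteria. The 25 lists with at least 5 tested members were tested with camera (preset correlation 0.01, and a correlation estimated per list) and fry, and a gene may stand in several lists. Camera compares a list with the other genes, and fry asks whether its members move on balance in one direction. Each list's median was also placed among 10000 random lists of the same size, drawn from 20 bins of mean expression, or from 5 bins of expression and 8 of locus length. The pattern for MAPK, PI3K, TOR and Ras signalling matched parts of words such as factor and facilitator, and 6 lists were run again with tightened patterns.

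Named genes follow a rule with 4 parts. These are the 12 highest and 12 lowest genes by the smallest of 3 EGF ratios of the same sign, the 4 highest and 4 lowest ratios at each time, the 8 highest and 8 lowest significant changes from 96 h to 120 h, and up to 4 members per list with the largest mean EGF ratio of the same sign at all 3 times. The first 2 parts ask for a product name and a mean of at least 5 FPKM. Added after the data were examined were the 8 highest and 8 lowest genes with a product name in 108 h and in 120 h against 96 h, list members that passed the time test, and genes of the cell cycle 2-fold higher with EGF at 108 h. The list tests of 108 h against 96 h and of 120 h against 108 h, the fits without each library in turn, the tightened patterns and a loess correction of each library for locus length (span 0.3) were also added then.

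The alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, libraries scaled to a median log2 ratio of 0, quantile normalization, limma without the trend, no time block, an adjusted p threshold of 0.1, fold thresholds of 1.5 and 4, and each pair or library left out. No scaling moved the median of all genes by more than 0.04 on the log2 scale. The steps were tested on simulated data with 200 of 16577 genes changed: for the EGF effect limma recovered 99% of 100 genes changed 2-fold and 100% of 100 changed 4-fold, with 17 false among 216 calls. For 108 h against 96 h it recovered 91% and 100%, with 18 false among 209 calls. Of 5 simulated lists of 60 members moved by 0.5, camera called 5, and of 20 unchanged lists 0. The simulated noise was independent between genes, and the simulated EGF change was equal at all 3 times. The noise had the variances that limma had already drawn toward a common trend, which are more alike between genes than the observed ones. The shares recovered may therefore be too high for the real data. Neither lists whose members vary together nor EGF changes at single times were simulated, so that these shares do not carry over to them. R 4.3.3 with limma 3.58.1 and matrixStats 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.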

Results

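Messenger RNA of the hypotrich ciliate Stylonychia lemnae was sequenced in 6 libraries. Control cultures and cultures given 10 µg/ml human epidermal growth factor (EGF) were taken at 96 h, 108 h and 120 h. There was 1 library per treatment and time point, each made from RNA pooled from 3 cultures, so that no library has a replicate. Expression was deposited as FPKM for 21061 genes, of which 12739 (60.5%) are described only as a hypothetical protein. The somatic genome of this ciliate consists of gene-sized chromosomes, and positions are given below on the assembly's contigs in bp counted from 1, without a named genome build. The FPKM of a library summed to 1235910 in the control and 1173864 with EGF at 96 h, to 1308095 and 1281711 at 108 h, and to 1021114 and 972181 at 120 h. Read counts were not used here. The value that 1 fragment takes at the same locus put the depths of the libraries at 0.931 to 1.55 times that of the control at 96 h, or roughly 10800000 to 17100000 fragments, at which 5 FPKM in a locus of 1 kb correspond to about 54.2 to 85.5 fragments.

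Libraries lay nearer by time than by treatment. The Pearson correlation of log2(FPKM + 1) across 16577 genes averaged 0.985 over the 3 pairs of the same time (0.982 to 0.991). It averaged 0.958 over the 6 pairs of the same treatment and 0.957 over the 6 pairs that shared neither. The first principal component held 53.8% of the variance and set the control at 108 h (59.5) and EGF at 108 h (33.1) apart from the control (-35.5) and EGF (-34.9) at 96 h. The control (-0.88) and EGF (-21.3) at 120 h lay between them on this component. The second component held 27.5% of the variance. It set the control (-39.8) and EGF (-27.9) at 120 h apart from the other libraries (1.54 to 26.3). With 1 library per condition and time, the distance between replicates is unknown.

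The study compared EGF with control cultures. Higher with EGF at 96 h, among genes with a product name and a mean of at least 5 FPKM, were a gene described as splice (Contig3716.g3971, 1.17 FPKM in the control and 31.0 FPKM with EGF) and F-box domain genes, whose products select proteins for ubiquitin-dependent destruction. The F-box gene Contig17038.g18144 stood at 8.01 FPKM in the control and 42.7 FPKM with EGF, and Contig15023.g16007 at 46.2 and 163 FPKM. An ABC transporter (Contig7741.g8249, mean 2.19 FPKM) stood at 2.33 and 10.2 FPKM. Lower with EGF at 96 h were luminal binding protein, a chaperone of the endoplasmic reticulum (Contig13562.g14471, 1172 and 653 FPKM), and both B9 domain genes, known from the base of cilia. B9 domain-containing protein 1 (Contig1323.g1454) stood at 6.83 and 3.32 FPKM and B9 domain-containing protein 2 (Contig5571.g5964) at 6.70 and 3.43 FPKM. Of 16577 genes, 93 were at least 2-fold higher and 21 at least 2-fold lower with EGF at 96 h.

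At 108 h a histone H3 gene (Contig13116.g13984, positions 66 to 720) stood at 148 FPKM in the control and 561.2 FPKM with EGF, while another (Contig3614.g3856) stood lower with EGF, at 121 and 58.4 FPKM. Cyclin 2 (Contig15535.g16555), of the family that drives kinases of the cell cycle, stood at 5.24 and 16.7 FPKM. A tubulin beta chain (Contig18567.g19735), a subunit of microtubules, stood at 244 and 588 FPKM. An EF hand gene (Contig6183.g6611), a calcium-binding family, stood at 10.6 and 31.6 FPKM. Lower with EGF at 108 h were myc binding protein 2 (Contig5091.g5442, 191 and 69.6 FPKM) and 2 genes of small-RNA synthesis and processing. These were the smallest subunit of RNA polymerase III (Contig2977.g3186, 45.6 and 17.2 FPKM) and a subunit of RNase P and RNase MRP (Contig7915.g8449, 26.7 and 9.86 FPKM). At least 2-fold higher were 147 genes and at least 2-fold lower 151 genes, or 196 and 75 after a correction for locus length that was chosen after the data were seen. The 147 include a hypothetical protein of 7289 bp (Contig11071.g11842, positions 117 to 7405) that was singled out after its values were seen. It is listed at 0 in the 3 control libraries and in EGF at 96 h, and at 4509 FPKM with EGF at 108 h and 4123 FPKM with EGF at 120 h. The table gives no status per value, so that these 0 values cannot be read as absence of the transcript, and the locus may have been left unquantified in 4 libraries.

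At 120 h a lipase (Contig5597.g5992), an enzyme that splits fats, stood at 6.96 FPKM in the control and 33.8 FPKM with EGF. A MAPK-related kinase (Contig9678.g10347, positions 156 to 1730), of a family that relays growth and stress signals, stood at 47.7 and 157 FPKM. A gene of the gpr1/fun34/yaaH family, known as acetate and ammonium transporters in other organisms (Contig12573.g13414), stood at 12.2 and 39.7 FPKM. Lower with EGF were a protein kinase (Contig1844.g1997, 23.7 and 7.55 FPKM) and a gene named after the interferon-inducible protein gig2 (Contig12244.g13080, 36.4 and 12.5 FPKM), which at 96 h had been higher with EGF, at 5.65 and 21.5 FPKM (log2 ratio 1.76). At 120 h, 80 genes were at least 2-fold higher and 85 at least 2-fold lower, or 98 and 37 after the correction for locus length. These counts per time have no test, since each rests on 1 pair of libraries, and they moved with the pseudocount, from 42 to 310 genes at 96 h, from 89 to 815 at 108 h and from 50 to 382 at 120 h for pseudocounts of 5 and 0.1.

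Medians of gene lists at single times were placed among 10000 random lists of like expression, which describes 1 pair of libraries each and is no test of EGF, since members of a list vary together. At 96 h the 108 ribosomal proteins had a median log2 ratio of -0.22 (percentile 0; 18 members higher with EGF) and the 53 genes of DNA replication one of -0.15 (percentile 0.03; 17 higher). The 168 genes of cilia and axoneme had a median of -0.10 at 96 h (percentile 0) and of 0.21 at 108 h (percentile 100; 115 higher). The 83 genes of cell cycle and mitosis had a median of 0.18 at 108 h (percentile 100; 53 higher) and of -0.14 at 120 h (percentile 0.26; 27 higher). The 305 lysosomal hydrolases and proteases had a median of -0.07 at 96 h and 0.14 at 108 h (percentile 100; 191 higher). Among the 118 genes of vesicle traffic and the V-ATPase the median at 108 h was -0.18 (percentile 0.44; 34 higher), with the R-SNARE Contig3110.g3329, a vesicle fusion protein, at 48.0 and 25.0 FPKM. All 11 autophagy genes but 1 were lower with EGF at 108 h (median -0.35, percentile 2.45), among them the atg1-like kinase Contig13560.g14469 at 116 and 81.1 FPKM. The 6 genes of the food alga list, whose names point to another organism, had a like median at 108 h (-0.36, percentile 6.21; 0 higher). The values named here kept their sign under all scalings.

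Across the 3 times, actin I (Contig12113.g12949, positions 166 to 1344), the subunit of actin filaments, was higher with EGF in every pair. It stood at 327 and 450 FPKM at 96 h, 378 and 578 FPKM at 108 h, and 108 and 166 FPKM at 120 h, a mean log2 ratio of 0.56 ± 0.14 (SE, n = 3 pairs, limma adjusted p = 0.826). Other genes higher with EGF in all 3 pairs included the F-box gene Contig17038.g18144 (mean log2 ratio 1.17), the lipase Contig5597.g5992 (1.18), ADP/ATP translocase 2 of the mitochondrial membrane (Contig9064.g9697, 0.87) and a mitochondrial fumarase-like gene of the citric acid cycle (Contig18382.g19523, 0.65). Genes lower with EGF in all 3 pairs included rab11 (Contig8478.g9048), a small GTPase of recycling vesicles, at 9.97 and 7.50, 19.9 and 11.2, and 12.4 and 7.76 FPKM. The beta subunit of the translation initiation factor eIF-2B (Contig17706.g18820) stood at 8.93 and 5.00, 19.7 and 15.1, and 9.79 and 6.84 FPKM. Sideroflexin-5 (Contig11811.g12627), a mitochondrial carrier, had log2 ratios of -0.32, -0.31 and -0.31. With time as a block, limma called 0 of 16577 genes (lowest adjusted p = 0.826). At an unadjusted p under 0.05 it found 927, where 829 are the number given by chance. Ratios of the same sign at all 3 times were seen in 4196 genes (25.3%, where chance gives 25%), and at least 1.5-fold at all 3 times in 2 genes higher and 4 lower. Without the 120 h pair 48 genes passed, 43 of them higher with EGF. The lowest p was that of Contig11071.g11842, whose ratios were 0 and 12.1 and whose 0 values are in doubt, so that a gene apart at 1 time can pass this fit. Its SE was 0.273, and that of the splice gene, with ratios of 3.88 and 0.91, was 0.26. The SE in this fit thus hardly followed a gene's own spread between pairs, and the 48 calls are no sign of a repeated EGF change. Also passing were histone H3 Contig13116.g13984, the splice gene, the F-box gene Contig17038.g18144 and the piwi-like gene Contig18901.g20051. Without the 96 h pair 1 gene passed (Contig11071.g11842 again), and without the 108 h pair 0 did. At an unadjusted p under 0.05 limma found 3316 genes without the 96 h pair, 489 without the 108 h pair and 515 without the 120 h pair. The 3316 lie above the 829 given by chance. Genes are not independent, and the ratios at 108 h and 120 h both went with locus length, so that this excess is no test of EGF.

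**Figure D1:**
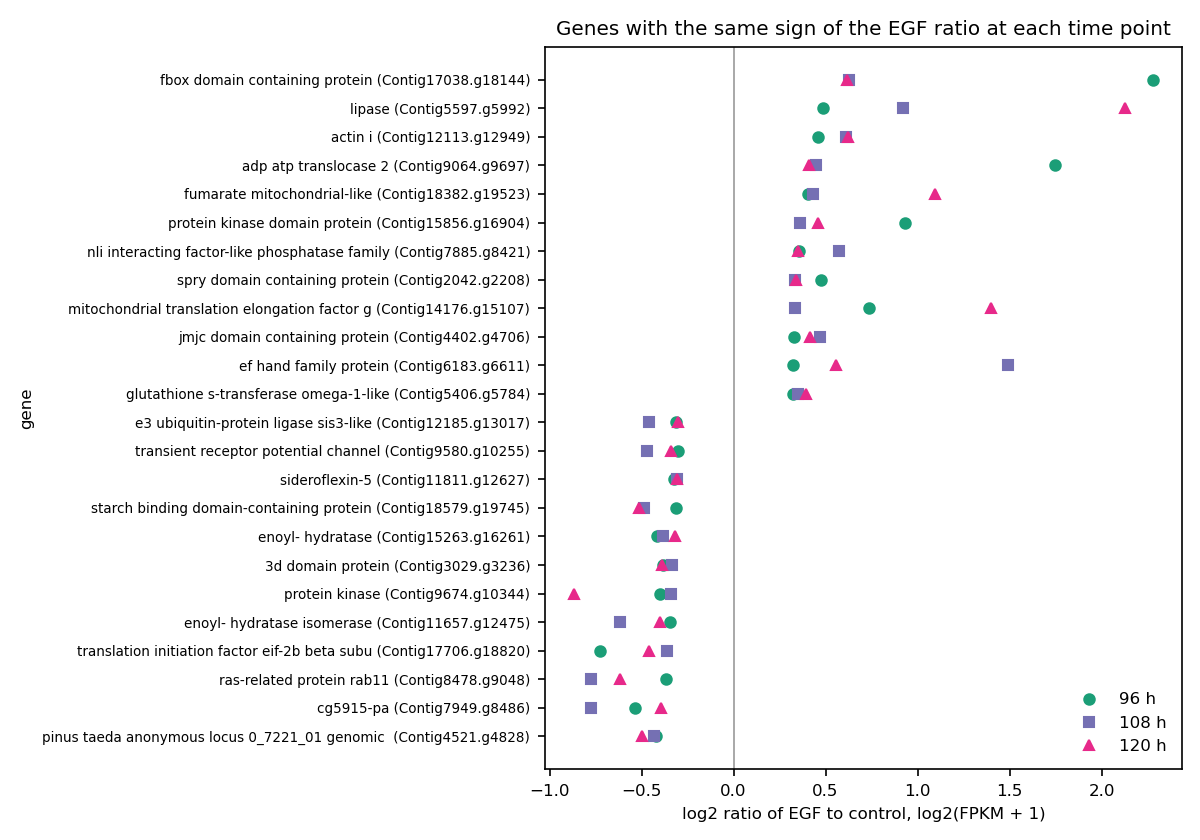
Log2 ratio of EGF to control (x axis) at 96 h, 108 h and 120 h, 1 point per pair of libraries, for the 12 named genes highest and the 12 lowest by the smallest of the 3 ratios. Every gene has 3 points on the same side of 0, and none of the 24 passed the test over the time points.

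Among 25 gene lists tested over the 3 times, camera with its preset correlation called 7, and with an estimated correlation 0 (lowest adjusted p = 0.835). Ribosomal proteins were lower with EGF as a list (median log2 ratio -0.13, adjusted p = 5.05e-06, and adjusted p = 0.835 with an estimated correlation), with the abundant acidic protein P1 (Contig1593.g1736) at 3564 and 3080 FPKM at 96 h, 5157 and 4350 FPKM at 108 h, and 3379 and 2511 FPKM at 120 h. At 108 h alone the ribosomal median was -0.03 (50 of 108 higher), and the locus length correction turned it to 0.18 at 108 h, turned -0.18 to 0.01 at 120 h and moved -0.22 to -0.28 at 96 h. Vesicle traffic and the V-ATPase were lower (-0.12, adjusted p = 0.0076, and adjusted p = 0.835 with an estimated correlation). Higher were the 10 genes of small RNA and genome rearrangement (0.17, adjusted p = 0.0141, and adjusted p = 0.835 with an estimated correlation). They include the piwi-like gene Contig5402.g5780, of the family that carries small RNAs in genome rearrangement, at 2.47 and 4.04, 0.48 and 2.30, and 2.92 and 5.88 FPKM. Also higher were kinesins and myosins (0.09, adjusted p = 0.015), the 547 protein kinases (0.04), lysosomal hydrolases and proteases (0.06) and the 245 genes of cyclic nucleotide and calcium signalling (0.06), with an adjusted p of 0.835 to 0.847 with an estimated correlation. Of these 7 calls the locus length correction left 1, vesicle traffic and the V-ATPase (-0.07, adjusted p = 0.0275). It ended those of ribosomal proteins (-0.04, adjusted p = 0.473), small RNA and genome rearrangement (0.10, adjusted p = 0.139), lysosomal hydrolases and proteases (0.06, adjusted p = 0.0746), kinesins and myosins (0.01, adjusted p = 0.854), protein kinases (0.01, adjusted p = 0.625) and cyclic nucleotide and calcium signalling (0.01, adjusted p = 0.334). It brought calls on DNA replication (-0.14, adjusted p = 0.0206) and on redox and detoxification, whose median turned from -0.01 to 0.05 (adjusted p = 0.0371). No member of any list passed over all genes, and adjusted over the list alone 2 genes passed, both in small RNA and genome rearrangement. The 634 genes matched by the pattern for MAPK, PI3K, TOR and Ras signalling, the pathways below animal EGF receptors, had a median of -0.02 (adjusted p = 0.783). That pattern also took in elongation factors, other factors and motor proteins, and 223 genes under tightened names had a median of -0.05 (adjusted p = 0.198). The 4 genes with EGF-like or growth factor names were too few for a test, with median EGF ratios of 0.10 at 96 h (4 higher), 0.06 at 108 h (2 higher; -0.06 after the locus length correction) and 0.17 at 120 h (3 higher). The list calls fell to 4 without the 108 h pair, to 4 with quantile normalization, to 3 after the locus length correction, to 2 without the filter and to 0 with fry. The test of a treatment effect that grows or shrinks in a straight line with time called 0 genes with limma. At an unadjusted p under 0.05 it found 42, where 829 are the number given by chance. The fit takes time itself as a straight line, so that a peak or dip at 108 h counts as spread. Its 0 calls therefore do not show that the EGF effect was steady over time.

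The comparison of 108 h with 96 h, over both treatments, asks how the cultures moved in 12 h. In this and the other time contrasts, a difference in harvest or preparation shared by both libraries of a time cannot be told apart from time. Chaperonins and elongation factors were among the risen genes, picked singly and not tested as a group. The chaperonin cpn60 (Contig7264.g7767, positions 126 to 1995), which folds proteins inside mitochondria, rose from 29.2 to 243 FPKM in the control and from 24.8 to 297 FPKM with EGF, a log2 change of 3.27 ± 0.20 (SE, n = 2 libraries per time, adjusted p = 0.0002). Its partner of 10 kDa (Contig4165.g4448) rose by 2.29, and a further chaperone (Contig17951.g19080) by 3.28. Elongation factors Ts (Contig16618.g17705) and Tu (Contig6351.g6806), which serve the ribosomes of mitochondria and bacteria, rose by 3.23 and 2.91. Single genes that copy, cap and pack chromosomes were among the risen too. The alpha telomere binding protein (Contig10864.g11606, positions 126 to 1800), which caps chromosome ends in these ciliates, rose by 2.58 ± 0.19 (adjusted p = 0.000231). Ribonucleoside-diphosphate reductase (Contig14818.g15784), the source of DNA precursors, rose by 2.11, the small subunit of DNA primase (Contig10274.g10960), which starts new strands, by 1.85, histone H2B (Contig10417.g11107) by 2.24 and histone H4 (Contig8089.g8626) by 2.22.

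Other genes fell between 96 h and 108 h. The MAPK-related kinase (Contig9678.g10347) fell from 748 to 27.1 FPKM in the control and from 714 to 40.4 FPKM with EGF, a log2 change of -4.42 ± 0.35 (adjusted p = 0.000252). A RING1-like E3 ubiquitin ligase (Contig6238.g6672, positions 166 to 1440) changed by -2.99 and transcription factor MTF-1 (Contig15685.g16707), known as a sensor of metal ions, by -2.79. Single genes of ribosomes and their assembly fell, although more ribosomal proteins rose than fell (22 and 3, or 10 and 2 under tightened names) and the ribosome biogenesis list had no call. The fallen genes include the pre-rRNA-processing protein pno1 (Contig8908.g9521, -2.56), nucleolar GTP-binding protein 1 (Contig15230.g16223, -2.13), tsr1 (Contig7749.g8259, -1.69) and 60S ribosomal protein L24 (Contig5051.g5411, -2.12). Eukaryotic release factor 1 (Contig670.g747), which ends translation, changed by -1.91. In all, 2304 genes rose and 1887 fell of 16577, with 1642 genes in total without the control at 108 h, 2282 without the control at 96 h and 2548 without EGF at 108 h. Control and EGF cultures moved alike across genes (Pearson r of their changes 0.701 over 16577 genes, which are not independent replicates, 1 of 9 relations computed).

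**Figure D2:**
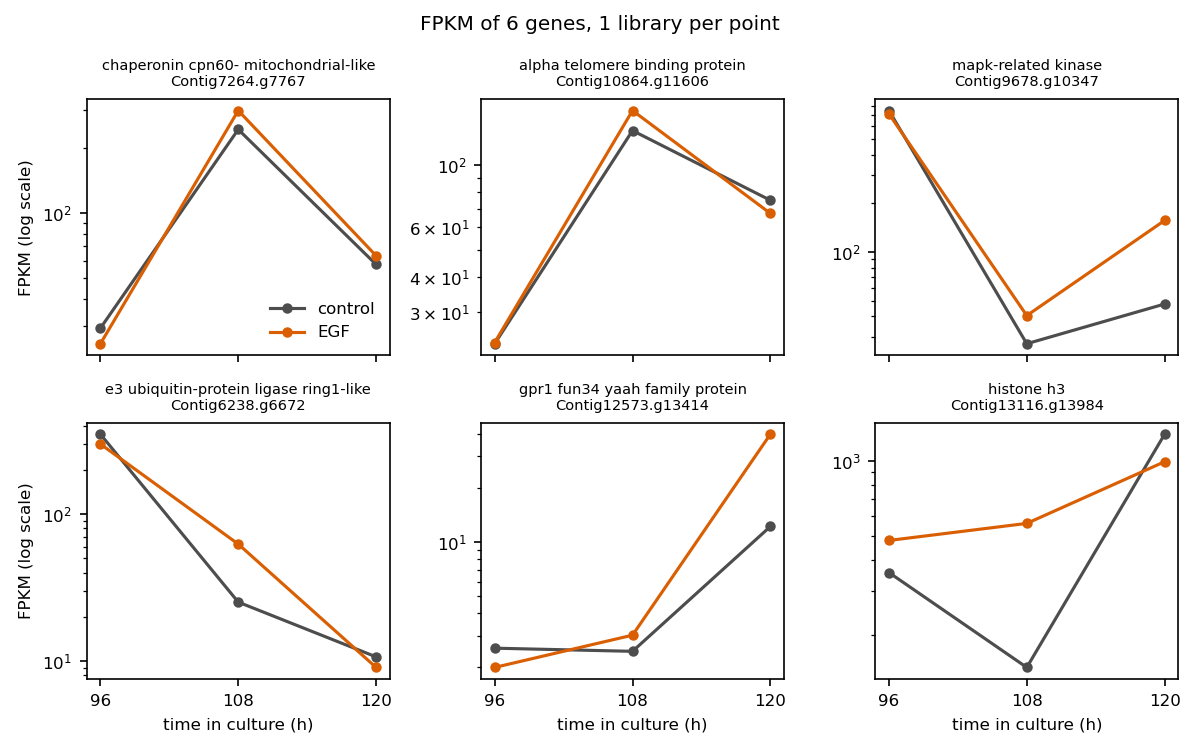
FPKM on a log axis against time in h for 6 genes in the control and EGF cultures, 1 point per library. The chaperonin cpn60 goes from 29.2 to 243 FPKM and the MAPK-related kinase from 748 to 27.1 FPKM between 96 h and 108 h in the control.

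By list, 29 of 53 genes of DNA replication rose from 96 h to 108 h and 1 fell (adjusted over the list alone, 32 and 2), with a median log2 change of 0.68 (camera adjusted p = 2.05e-09, and adjusted p = 0.279 with an estimated correlation). Of 30 genes of glycolysis and gluconeogenesis 18 rose and 0 fell (adjusted over the list alone, 21 and 0; median 0.86; adjusted p = 1.13e-07, and adjusted p = 0.279 with an estimated correlation). They include glyceraldehyde 3-phosphate dehydrogenase (Contig7996.g8528, 1.51), aldolase (Contig16882.g17981, 1.44) and pyruvate kinase (Contig3887.g4149, 1.41), the glucose-splitting route. Of 98 heat shock proteins and chaperones 33 rose and 5 fell (adjusted over the list alone, 42 and 7; median 0.48; adjusted p = 1.07e-06, and adjusted p = 0.279 with an estimated correlation). An HSP90 gene rose (Contig4071.g4352, 2.14) and another fell (Contig14368.g15308, -2.17). Of 15 histones 8 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.82; adjusted p = 0.00446, and adjusted p = 0.432 with an estimated correlation), and without the filter the histone median was -0.02 (adjusted p = 0.0934). Of 124 redox and detoxification genes 42 rose and 15 fell (adjusted over the list alone, 46 and 16; median 0.40; adjusted p = 0.000471, and adjusted p = 0.279 with an estimated correlation), such as betaine-aldehyde dehydrogenase (Contig9138.g9778, 2.02) and glutathione peroxidase (Contig12556.g13401, -1.62). The 20 genes that the bacterial pattern found are all named as 30S or 50S ribosomal proteins, the type mitochondria carry too. Of these 11 rose and 1 fell (adjusted over the list alone, 16 and 1; median 0.66; adjusted p = 7.54e-05, and adjusted p = 0.279 with an estimated correlation), such as S17 (Contig675.g755, 1.36).

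Of 118 genes of vesicle traffic and the V-ATPase 30 rose and 2 fell between 96 h and 108 h (adjusted over the list alone, 31 and 2; median 0.34; adjusted p = 0.000598, and adjusted p = 0.42 with an estimated correlation), such as the synaptobrevin Contig507.g563 (1.31). Of 86 genes of the citric acid cycle and oxidative phosphorylation 18 rose and 4 fell (18 and 4 adjusted over the list alone; median 0.31; adjusted p = 0.00359, and adjusted p = 0.549 with an estimated correlation). They include isocitrate dehydrogenase (Contig6173.g6601, 1.26) and cytochrome c (Contig3380.g3619, 1.21), but also subunit H of the vacuolar ATPase (Contig19160.g20319, 1.36), which acidifies vacuoles. Of 105 lipid genes 23 rose and 5 fell (adjusted over the list alone, 25 and 5; median 0.27; adjusted p = 0.0328, and adjusted p = 0.312 with an estimated correlation), with a delta isomerase of fatty acid breakdown up (Contig11580.g12396, 3.29) and peroxisomal membrane protein 2 down (Contig10790.g11539, -2.60). Of 108 ribosomal proteins 22 rose and 3 fell (22 and 3 adjusted over the list alone; median 0.23; adjusted p = 0.000509, and adjusted p = 0.677 with an estimated correlation), and the locus length correction left a median of 0.04 (adjusted p = 0.208). Of the 22 risen, 11 are the 30S and 50S proteins above, and under tightened names 10 of 84 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.18; adjusted p = 0.023, and adjusted p = 0.751 with an estimated correlation). Protein kinases moved the other way, with 39 of 547 risen and 116 fallen (adjusted over the list alone, 42 and 119; median -0.19; adjusted p = 0.00116, and adjusted p = 0.42 with an estimated correlation), such as the kinase domain gene Contig15404.g16425 (-2.68). Of 85 kinesins and myosins 3 rose and 16 fell (3 and 16 adjusted over the list alone; median -0.19; adjusted p = 0.00757, and adjusted p = 0.432 with an estimated correlation). Several of the fallen members are myosin light chain kinases (Contig15920.g16971, -1.57), which are kinases and not motors, and the locus length correction left a median of -0.02 (adjusted p = 0.495). Quantile normalization ended the calls on the citric acid cycle and oxidative phosphorylation (0.19, adjusted p = 0.0608) and lipid genes (0.19, adjusted p = 0.116), and brought one on proteasome and ubiquitin (-0.23, adjusted p = 0.0106). The vesicle median was 0.20 with it and 0.22 after the locus length correction, which also ended the call on histones (0.55, adjusted p = 0.0579). With fry 6 of the 25 lists passed at 108 h against 96 h, and each of the 12 calls of camera was lost with an estimated correlation.

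The larger lists without a call held genes moving both ways from 96 h to 108 h. Among 90 translation factors and tRNA synthetases 30 rose and 20 fell (adjusted over the list alone, 33 and 21; median 0.15; camera adjusted p = 0.187). Elongation factors Ts and Tu rose, while a lysyl-tRNA synthetase (Contig7684.g8193, -1.87) and the phenylalanyl-tRNA synthetase beta chain (Contig15971.g17019, -1.73), which load tRNAs, fell. Among 38 genes of ribosome biogenesis 3 rose and 8 fell (3 and 8 adjusted over the list alone; median 0.02; adjusted p = 0.539). Of 83 genes of cell cycle and mitosis 9 rose and 11 fell (10 and 12 adjusted over the list alone; adjusted p = 0.838). The replication initiation gene cdc45 (Contig3704.g3956) rose by 1.85 and the p34-cdc2 kinase (Contig19150.g20309) changed by -1.73. The list took in ribosome recycling factor (Contig2946.g3148, 1.88), which acts in translation, by the letters of its name. In the 168 genes of cilia and axoneme 24 rose and 17 fell (23 and 17 adjusted over the list alone), among the fallen a tubulin-tyrosine ligase-like gene (Contig13567.g14477, -1.77), which modifies tubulin. Tightened names, without such enzymes, left 105 genes of cilia and axoneme, with 21 risen and 3 fallen (20 and 3 adjusted over the list alone; median 0.24; adjusted p = 0.0113, and adjusted p = 0.72 with an estimated correlation). Of the 226 proteasome and ubiquitin genes 15 rose and 23 fell (14 and 18 adjusted over the list alone; median -0.14; adjusted p = 0.069). In the 305 lysosomal hydrolases and proteases 43 rose and 30 fell (42 and 29 adjusted over the list alone), with an acid phosphatase up (Contig12513.g13353, 2.46) and cathepsin B down (Contig2725.g2927, -1.53). Of 341 transporters and ion channels 24 rose and 36 fell (17 and 23 adjusted over the list alone; median -0.08; adjusted p = 0.187), and of 245 cyclic nucleotide and calcium genes 18 rose and 21 fell (16 and 19 adjusted over the list alone), such as a cAMP-dependent protein kinase (Contig19325.g20493, -1.95). The pattern for MAPK, PI3K, TOR and Ras signalling had 91 risen and 63 fallen (89 and 63 adjusted over the list alone), with elongation factors Ts and Tu among the risen. Small counts were found in meiosis and DNA repair (1 of 17 risen; 0 adjusted over the list alone), small RNA and genome rearrangement (2 of 10 fallen; 2 adjusted over the list alone) and autophagy (1 of 11 risen; 1 adjusted over the list alone). The food alga list held 6 genes, of which 1 rose, a single-stranded DNA-binding protein with a chloroplast-type name (Contig3099.g3313, 1.70; 1 adjusted over the list alone). Its median change was 0.41 (camera adjusted p = 0.248), with 0.66 in the control (5 of 6 higher) and 0.10 with EGF (4 of 6 higher). Of the 4 growth factor names 1 fell, the hepatocyte growth factor-regulated kinase substrate (Contig10932.g11684, -0.72; 1 adjusted over the list alone).

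**Figure D3:**
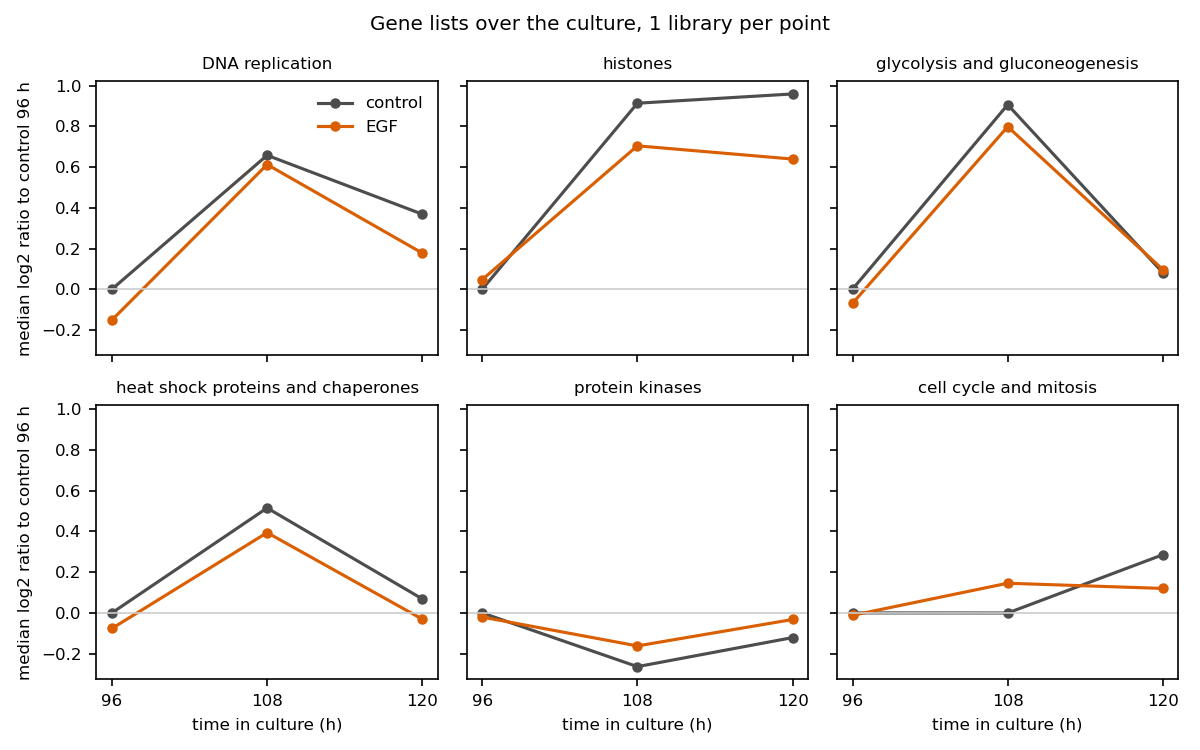
Median log2 difference from the control library of 96 h (y axis) against time in h for 6 gene lists in control and EGF cultures, 1 point per library. Genes of DNA replication and glycolysis stand highest at 108 h in both cultures, with medians of 0.66 and 0.91 in the control and 0.37 and 0.08 in the control at 120 h.

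From 96 h to 120 h a smaller set of genes moved. A gene of the gpr1/fun34/yaaH family (Contig12573.g13414, in the control 2.56 FPKM at 96 h and 12.2 FPKM at 120 h) rose by 2.83 ± 0.37 (SE, n = 2 libraries per time, adjusted p = 0.00505). A ligand-gated ion channel gene (Contig5391.g5764), of the family that opens on binding a transmitter, rose by 2.20, and its neighbour on the contig, a hypothetical protein (Contig5391.g5765), by 2.64. The hypothetical proteins Contig15799.g16842 and Contig15799.g16843, which share a contig, rose from 0.98 to 40.5 FPKM and from 21.6 to 229 FPKM in the control (log2 change of the latter over both treatments 3.44). The kinase nek2 (Contig7728.g8236), of centrosome separation, rose by 1.59 and the cohesin gene rad21 (Contig17875.g18998) by 1.41. The RING1-like E3 ubiquitin ligase (Contig6238.g6672) fell from 350 to 10.7 FPKM in the control and from 300 to 9.07 FPKM with EGF, a log2 change of -4.90 ± 0.34 (adjusted p = 0.000643). The hypothetical protein Contig3856.g4124 changed by -6.15, the MAPK-related kinase (Contig9678.g10347) by -3.06, a piwi-like gene (Contig18901.g20051) by -3.05 and actin I (Contig12113.g12949) by -1.51. In all 597 genes rose and 768 fell, a balance that turned to 793 and 760 with quantile normalization. The total of 1365 was 216 without the control at 96 h, 292 without the control at 120 h, 825 without EGF at 96 h, 510 without the filter and 891 with a mean of at least 5 FPKM.

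Between 96 h and 120 h camera called 9 lists, and 0 with an estimated correlation. Of 53 genes of DNA replication 10 rose and 0 fell (adjusted over the list alone, 14 and 3; median 0.26; camera adjusted p = 0.000127, and adjusted p = 0.317 with an estimated correlation). Of 15 histones 7 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.69; adjusted p = 0.000922, and adjusted p = 0.635 with an estimated correlation). Of 83 genes of cell cycle and mitosis 13 rose and 7 fell (adjusted over the list alone, 27 and 7; median 0.18; adjusted p = 0.00273, and adjusted p = 0.635 with an estimated correlation), with the cyclin-dependent kinase b2-2-like gene (Contig7267.g7771) at -2.13. Of 168 genes of cilia and axoneme 5 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.17, or 0.25 for 105 genes under tightened names; adjusted p = 0.000608, and adjusted p = 0.635 with an estimated correlation). Cyclic nucleotide and calcium genes had 15 risen and 8 fallen of 245 (18 and 9 adjusted over the list alone; median 0.09; adjusted p = 0.0417, and adjusted p = 0.635 with an estimated correlation). Redox and detoxification genes had 2 risen and 21 fallen of 124 (adjusted over the list alone, 2 and 28; median -0.28; adjusted p = 2.77e-05, and adjusted p = 0.317 with an estimated correlation), such as glutathione S-transferase pi 1 (Contig18200.g19342, -1.32). Proteasome and ubiquitin genes had 1 risen and 12 fallen of 226 (1 and 8 adjusted over the list alone; median -0.26; adjusted p = 3.18e-05, and adjusted p = 0.317 with an estimated correlation). Of 90 translation factors and tRNA synthetases 0 rose and 11 fell (1 and 15 adjusted over the list alone; median -0.21; adjusted p = 0.00333, and adjusted p = 0.635 with an estimated correlation). Ribosomal proteins had a median of -0.26 (0 risen and 2 fallen of 108, 0 and 0 adjusted over the list alone; adjusted p = 0.000127, and adjusted p = 0.635 with an estimated correlation), which turned to 0.05 with quantile normalization (adjusted p = 0.325). That setting also ended the call on translation factors and tRNA synthetases (-0.07, adjusted p = 0.121), and no filter ended those on histones (0.09, adjusted p = 0.117) and cyclic nucleotide and calcium genes (0.10, adjusted p = 0.0729). With fry 0 lists passed (lowest adjusted p = 0.0924).

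From 108 h to 120 h 1164 genes rose and 1934 fell, and 9 of the 10 lists called up at 108 h were called down by camera. Both contrasts use the 108 h libraries, with opposite sign, so that these falls are no independent sign of a return. Histones were not called (median -0.35, 3 risen and 6 fallen of 15, 3 and 7 adjusted over the list alone; adjusted p = 0.106). Glycolysis and gluconeogenesis had 0 risen and 16 fallen of 30 (adjusted over the list alone, 0 and 19; median -0.79; camera adjusted p = 1.80e-07, and adjusted p = 0.24 with an estimated correlation). Heat shock proteins and chaperones had 1 risen and 31 fallen of 98 (2 and 38 adjusted over the list alone; median -0.42; adjusted p = 1.03e-06, and adjusted p = 0.24 with an estimated correlation). DNA replication had 0 risen and 21 fallen of 53 (2 and 27 adjusted over the list alone; median -0.53; adjusted p = 3.51e-06, and adjusted p = 0.24 with an estimated correlation). Redox and detoxification had 3 risen and 56 fallen of 124 (5 and 65 adjusted over the list alone; median -0.55; adjusted p = 1.95e-12, and adjusted p = 0.232 with an estimated correlation). Ribosomal proteins had 1 risen and 32 fallen of 108 (1 and 57 adjusted over the list alone; median -0.47; adjusted p = 1.91e-12, and adjusted p = 0.333 with an estimated correlation). Protein kinases had 54 risen and 23 fallen of 547 (39 and 13 adjusted over the list alone; median 0.17; adjusted p = 0.00354, and adjusted p = 0.34 with an estimated correlation). The locus length correction ended the call on protein kinases (0.11, adjusted p = 0.0892), and with quantile normalization the ribosomal median was -0.10 (adjusted p = 0.0418). Camera called 15 lists in this contrast, fry 10 and camera with an estimated correlation 0. The total of 3098 genes was 270 without the control at 108 h, 1022 without the control at 120 h and 1617 without EGF at 120 h. Over all 3 times the F test called 4985 genes, or 2107 without the control at 108 h.

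Locus length went with the EGF ratio. Across 16577 genes the Spearman correlation of the log2 ratio with locus length was -0.154 at 96 h, 0.350 at 108 h and 0.416 at 120 h. Loci of 209 to 875 bp, which include histones and ribosomal proteins, had median ratios of -0.26 at 108 h and -0.23 at 120 h, and loci of 3025 to 25955 bp had 0.18 and 0.16. In the control the change from 96 h to 108 h had a median of 0.44 in the shortest and -0.35 in the longest loci, against 0.10 and -0.07 with EGF. Genes are not independent replicates, and the length is that of the listed locus.

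**Figure D4:**
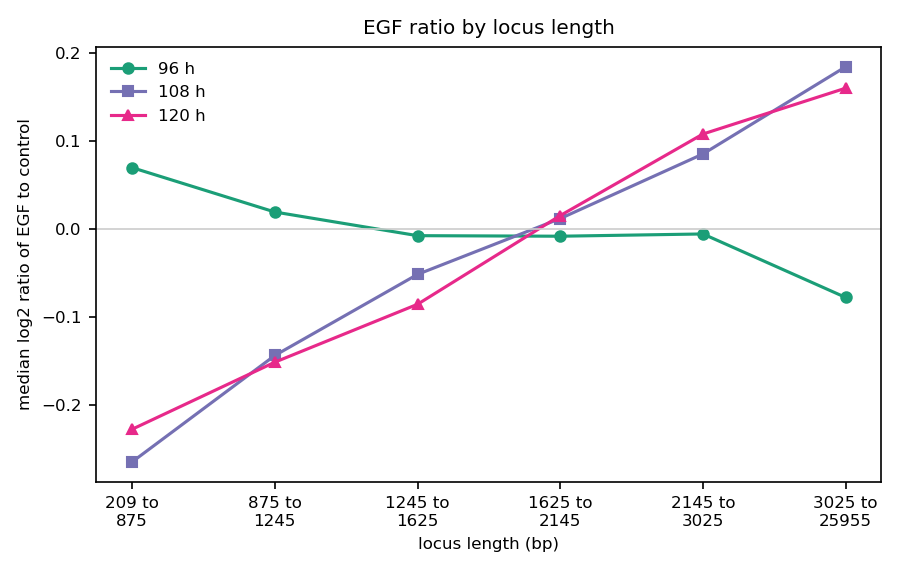
Median log2 ratio of EGF to control (y axis) in 6 bins of locus length in bp (x axis) at 96 h, 108 h and 120 h. The shortest bin lies at 0.07, -0.26 and -0.23 and the longest at -0.08, 0.18 and 0.16.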

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

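The tests of explanations and the limit to lists beyond both kinds of random lists were chosen after the results were seen, as were the 9 relations computed across genes, which are not independent of each other. In 3 gene lists the EGF ratio lay on opposite sides of 0 at different times, beyond what random lists of like expression and locus length gave, and the differences were not tested. For cell cycle and mitosis the median log2 ratio at 108 h minus that at 120 h was 0.325 (0.18 and -0.14). For cilia and axoneme 108 h minus 96 h gave 0.309 (0.21 and -0.10, or 0.11 and -0.05 after the locus length correction). For lysosomal hydrolases and proteases 108 h minus 96 h gave 0.21 (0.14 and -0.07).

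The genes at least 2-fold higher with EGF at 108 h include, besides a histone H3 and cyclin 2, cyclin b5 (Contig2803.g3003), the mitotic exit phosphatase cdc14a (Contig11539.g12344), the CDK regulatory subunits Contig10296.g10985 and Contig15459.g16475 and the Myb-type factor 3r-5 (Contig14288.g15216), picked by hand after their values were seen and not tested as a group. Without the gene listed at 0 in 4 libraries they number 146. Locus length as the whole cause is argued against by the size of its trend, whose bin medians at 108 h lay between -0.26 and 0.18. That 80.8% (118) stayed 2-fold higher after the correction follows from this size and adds no further support. An early rise above the 96 h level is argued against for the set, whose median change with EGF from 96 h to 108 h was 0.119. The middle 50% of these changes ran from -0.33 to 0.56, and 89 genes were higher, so that an early rise in some of them stays open. A candidate explanation for many of these genes is that they peak at 120 h and were low at 108 h in the control alone. The median control change of the 146 was -0.88 at 108 h, low by the choice of the genes, and 0.882 at 120 h, where random lists gave -0.11 to 0.08. The middle 50% of the control changes to 120 h ran from -0.22 to 1.52, and 105 genes were higher. Others took another course, such as heat shock protein 70 (Contig17050.g18159), at 1511, 651 and 659 FPKM in the control at 96 h, 108 h and 120 h. Cultures at another point of their growth, or 1 aberrant control library at 108 h, stay open, since no second control library of that time exists.

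The EGF ratios at 108 h and 120 h went together across genes (Pearson r = 0.449), although the pairs share no library. Locus length as the whole cause is argued against by an r of 0.369 after the correction. The data are consistent with a smaller change to 108 h and a faster return in the EGF cultures: the ratio at 120 h went with the control change from 96 h to 108 h at r = -0.475, with no shared library. The standard deviation of the change to 108 h was 0.764 in the control and 0.637 with EGF, and of that to 120 h 0.595 and 0.496. Preparation of control and EGF libraries on different days cannot be told apart from EGF with 1 library per treatment and time.

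Longer loci were higher with EGF at 108 h and 120 h. Short gene families known by name are argued against as the whole cause. Among 9345 genes with no product name, and so in no list, the lower of both rank correlations was 0.351. Genes without a name may belong to short families too, so that families among them stay open. A length-dependent difference between the libraries, such as RNA integrity or fragment size, may account for it: in 100% of the 19 lists with at least 30 members the rank correlation was above 0 at both times, though near 0 in some (0.103 and 0.0447 for redox and detoxification). A biological difference between long and short transcripts stays open and was not tested. Calls on lists of short genes, such as ribosomal proteins, rest on this trend in part (EGF median -0.13 before the correction and -0.04 after).

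The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The libraries are paired by time, and only splits with 1 library of each time in each group keep the pairs. For the EGF effect such splits gave 927 (the real one), 275, 355 and 2862 genes at an unadjusted p under 0.05. Over all 10 splits, most of which break the pairs, 4 gave at least the real 927, and the highest other gave 2862. That split turns the 96 h pair round, which points to a structure of the samples. The 96 h ratios ran against those at 108 h (r = -0.198) and 120 h (r = -0.114), or -0.158 and -0.064 after the locus length correction. For the interaction the splits that keep the pairs gave 42 (the real one), 33, 30 and 47 genes. Over all 10 splits, 8 gave at least the real 42, and the highest other gave 7597, a split that follows time. For the lists called by camera the splits that keep the pairs gave 7 (the real one), 3, 7 and 3. Over all 10 splits, 4 gave at least the real 7, and the highest other gave 7.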

How the results depend on the processing

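The locus length correction, the tightened names, fits without a library, and list tests of 108 h against 96 h and 120 h against 108 h were chosen after the data were seen. The named genes recomputed under the alternatives kept their direction. Their EGF ratios at single times kept their sign in the 56 values tried at each time, and their changes to 108 h passed in all 112 values tried. These genes were chosen as the most extreme in the same libraries, and no library was left out for these values. They therefore speak to the processing alone and not to how far the genes would repeat. Changes to 120 h passed in 201 values and missed in 2, the kinase Contig1844.g1997 (adjusted p = 0.0527) and glutathione S-transferase Contig10792.g11541 (adjusted p = 0.0688) without the filter. Of the 24 genes named for the same EGF sign at all 3 times, Contig17038.g18144 (1.45) and Contig9064.g9697 (1.10) gained a call, both without the 120 h pair. The SE of that fit hardly followed a gene's own spread between pairs. EGF over the times stayed at 0 genes in limma with every pseudocount, filter, scaling, threshold, trend and block tried (lowest adjusted p from 0.802 to 1, 75 to 1087 genes at an unadjusted p under 0.05), and gave 0 to 48 without a pair (48 without 120 h, 1 without 96 h). The fits without the 96 h, 108 h and 120 h pair gave 3316, 489 and 515 genes at an unadjusted p under 0.05. The interaction stayed at 0 genes (42 at an unadjusted p under 0.05 as reported) with a pseudocount of 0.1, without the filter, with quantile normalization and after the length correction. Each of these fits takes time as a straight line, so that this is no sign of a steady EGF effect. Where no reason is given below, the cause was not tested.

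Genes 2-fold apart at 96 h, 108 h and 120 h numbered 310, 815 and 382 with a pseudocount of 0.1, and 42, 89 and 50 with one of 5, which shrinks ratios of low values. They numbered 696, 2396 and 1436 at 1.5-fold and 13, 4 and 4 at 4-fold. At 96 h a mean of at least 5 FPKM gave 46. From 96 h to 120 h no filter gave 510 genes and a mean of at least 5 FPKM 891. Without 1 library, whose lone partner is assumed to vary like the rest, counts ran from 1642 to 4885 (108 h against 96 h), 216 to 1449 (120 h against 96 h), 270 to 4537 (120 h against 108 h) and 2107 to 5962 (F test); the lowest were without the control at 108 h, 96 h, 108 h and 108 h. The same-time minus same-treatment correlation of 0.0271 was 0.0415 with Spearman's rho.

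Lists called for EGF numbered 0 with an estimated correlation, 0 with fry, 2 without the filter, 4 with quantile normalization, 3 after the length correction and 4 to 8 without a pair (4 without 108 h). An estimated correlation gave 0 calls in each time contrast; fry gave 6 at 108 h against 96 h and 0 at 120 h against 96 h. Ribosomal proteins at 120 h against 96 h turned to 0.0455 with quantile normalization. Depth, roughly 10800000 to 17100000 fragments, leaves genes near 1 FPKM with few fragments.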

Other observations

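The tests, counts and genes in this part were chosen after the data were seen. The 93 genes at least 2-fold higher with EGF at 96 h are mostly nameless (71), as are most tested genes (9345 of 16577). Their loci are short (median 835 bp, against 1625 bp for tested genes). At 108 h 10 of them were again 2-fold higher with EGF, and at 120 h 0. The hypothetical proteins Contig3856.g4124 (54.1 and 271 FPKM at 96 h, 3.73 and 12.2 FPKM at 108 h, 0.75 and 0.70 FPKM at 120 h, control and EGF) and Contig16630.g17718 (34.1 and 151, 5.83 and 17.3, and 0.92 and 0.86 FPKM) are among them, as is the piwi-like gene Contig18901.g20051 (27.0 and 72.6, 8.94 and 16.6, and 4.18 and 4.79 FPKM).

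Histones H2B (Contig10417.g11107) and H4 (Contig8089.g8626) stood highest at 108 h, at 2838 and 3968 FPKM in the control against 627 and 821 FPKM at 96 h. The H3 genes Contig13116.g13984 and Contig3614.g3856 stood highest at 120 h in the control, at 1279 and 221 FPKM, and their EGF ratios at 108 h were 1.91 and -1.03. Other H3 genes took other courses, such as Contig14361.g15298 at 131, 105 and 130 FPKM in the control at 96 h, 108 h and 120 h. Besides the gpr1/fun34/yaaH gene named above, another rose from 96 h to 120 h (Contig19422.g20594, 2.02).

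Many contigs of this assembly carry a single gene: of 17368 contigs with a listed gene 14414 hold 1, 2364 hold 2 and 590 hold more. Neighbours such as Contig15799.g16842 and Contig15799.g16843 rose together, which raised the hypothesis that a contig changes as a unit. Across 1661 contigs with both genes tested, the Pearson r of the neighbours' changes from 96 h to 120 h was 0.201, above the -0.08 to 0.08 of 2000 shuffles but too low for the contig to be the main unit of change. The r was 0.117 from 96 h to 108 h, and for the EGF ratios 0.086 at 96 h, 0.108 at 108 h and 0.0655 at 120 h, the last within the shuffles, 5 effects in all. Genes at least 100 bp apart (783 contigs) gave 0.241 to 120 h. The fragment size of these paired-end libraries is not given, and a fragment may span such a gap. Fragments shared between neighbours therefore stay open.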
